A study of Drosophila melanogaster with 7 samples.

How the data were processed

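RNA immunoprecipitation sequencing (RIP-seq) was performed with an antibody against the HA tag on S2R+ cells, a haemocyte-like Drosophila melanogaster cell line derived from embryos. Per the labels, the libraries are empty-vector controls. The labels also name a FLAG-tagged and an HA-tagged construct, each with HA itself in the place of a protein, so which constructs the cells held, and whether any tagged product was made, is unclear. Expression was under the promoter of the metallothionein gene MtnA, which copper induces, and the cells had been kept with copper(II) sulfate at 0.35 mM over 24 hours. Total RNA was fragmented chemically and selected for sizes above a minimum given in the labels. All 7 libraries are biological replicates, numbered in the labels, of this 1 group. The labels do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be partly technical.

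Per the file headers and descriptions, the authors deposited 1 track per library of the normalized signal of all reads along the dm3 build of the fly genome. The aligner, its version, the filters and the rule for reads with several matches are not given in the sources used here. Every deposited signal value was a whole multiple (tolerance 0.001) of the smallest value in its file, in 100.0% of intervals. Summing signal times length, and dividing by the smallest value, gave 50 covered bases for each read. The values are therefore read coverage scaled to a per-million total of reads (RPM), with both strands combined, and the number of reads behind each file was recovered from them. Reads that matched several places cannot be recognised in such tracks. Copies of a repeat on the unplaced scaffolds may thus share or exclude reads by a rule that is not given.

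From the tracks, the read depth at each base was summed in bins of 1 kb and divided by the 50 bases of a read, which gives reads per bin. Shares are reads in a bin, region or chromosome over all reads of the library, in percent or RPM. Chromosome lengths were taken as the last covered position in any library, which gave 139.66 Mb over 14 chromosomes and scaffolds. Before the data were examined, a library was set to enter means and SDs if its signal covered at least 1% of that length. Replicate 6, with 0.252% covered, did not, and its values are given separately; the other 6 libraries are called usable. A stricter minimum of 10% leaves 5 deep libraries, which are replicates 1, 2, 3, 5 and 7.

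The following results were fixed in advance. Read density per base of X, chromosome 4, the heterochromatic scaffolds and the mitochondrial genome was compared with the mean density of the arms 2L, 2R, 3L and 3R within each library, as a log2 ratio. Each of these 4 comparisons was tested with a two-sided exact sign-flip permutation test over libraries, with Benjamini-Hochberg adjustment. The share of reads in the top 1% of bins and the share of bins with any signal described concentration. Agreement between libraries was Pearson's r and Spearman's rho across bins on log2(RPM + 1), with no p-value because bins are not independent replicates. Relations with depth were tested across the 7 libraries with exact permutation tests over all 5040 pairings. Named regions follow a rule: the 20 bins with the highest mean share (neighbouring bins joined), the 5 bins with the largest SD of log2 share among bins with a mean of at least 10 RPM, and the highest bin of each chromosome. Confidence intervals of single shares are exact binomial (Clopper-Pearson, 95%). They, and the limit of 3 reads for a count of 0, cover counting error only, since reads without molecular identifiers are not independent molecules.

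The planned analyses of annotated features, gene groups and cell type markers were not run, because no annotation of the dm3 build was at hand and coordinates were not converted between builds. Regions are given by their dm3 coordinates, 1-based, without gene names. Sequence of the regions was not analysed here. Libraries made with a tagged protein, or from input RNA, were not analysed here either, so no enrichment over another group was computed. The alternatives tried were other sets of libraries, bins of 10 kb, leaving out the top 1% of bins, another pseudocount, a filter on low values, leaving out M and U, and leaving out each library.

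The scripts were tested on simulated data. Reads with known densities, a spliced read, a removed intron and a confined window were recovered in 13 of 13 checks. Counts for the real bins were also drawn with counting error alone from the mean share at each library's depth, which shows how far libraries would differ by sampling. With 200 of 13294 bins of the arms and X changed 16-fold in simulated replicate 1, a rule of 8-fold apart from every other deep library found 99 of the lowered and 100 of the raised bins, with 0 false calls. The changed bins were drawn above a higher minimum share than the bins tested. Simulated libraries varied less than the real ones (median SD of log2 share 0.13 against 0.59). The false calls to be had in the real data are therefore not known. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.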

Results

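The 7 libraries record RNA that was recovered with an HA antibody from copper-treated S2R+ cells carrying an empty vector. In RIP-seq, RNA bound to a tagged protein is pulled down with an antibody against the tag and sequenced. An empty-vector library serves as the background for such experiments, as it is meant to hold what the antibody and the matrix recover without a tagged protein of interest. The libraries form 1 group, so the measurements describe which RNA made up this background and how far it varied between libraries. Depth differed widely: replicate 1 held 17522340 reads, replicate 7 held 8003741, replicate 3 held 6731889, replicate 2 held 5903614, replicate 5 held 4253417, replicate 4 held 903282 and replicate 6 held 10815. The signal of the usable libraries covered 13.8% ± 5.09 (SD, n = 6) of the summed chromosome length, from 4.65% in replicate 4 to 19.7% in replicate 1. No pair of libraries differed by as little as counting error of independent reads. Chi-square per bin, which such error alone would hold near 1, ranged from 3.87 for replicates 3 and 5 to 224.04 for replicates 1 and 7. The value rises with depth and with duplicate reads, so it does not rank how far pairs differ.

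The first question was how the background RNA was spread over the genome. The arms 2L, 2R, 3L and 3R and the X, which make up 85.2% of the summed length, held 68.5% ± 9.38 of the reads (SD, n = 6). Most of the rest came from small parts of the genome. U, the unplaced sequence of the assembly, held 20.8% ± 7.25 of the reads on 7.2% of the length, XHet, the assembled part of X heterochromatin, held 4.34% ± 1.61 on 0.14%, and the mitochondrial genome held 4.94% ± 3.53 on 0.014%. Replicate 1 had the lowest shares of all 3, with 9.94% on U, 1.18% on XHet and 0.532% on the mitochondrial genome. Replicate 7 had the highest mitochondrial share, 10.96%. YHet, the assembled part of Y heterochromatin, was almost empty, with 76 reads in replicate 1 and 0 reads in replicate 6, which allows a share of up to 0.0277% there.

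**Figure D1:**
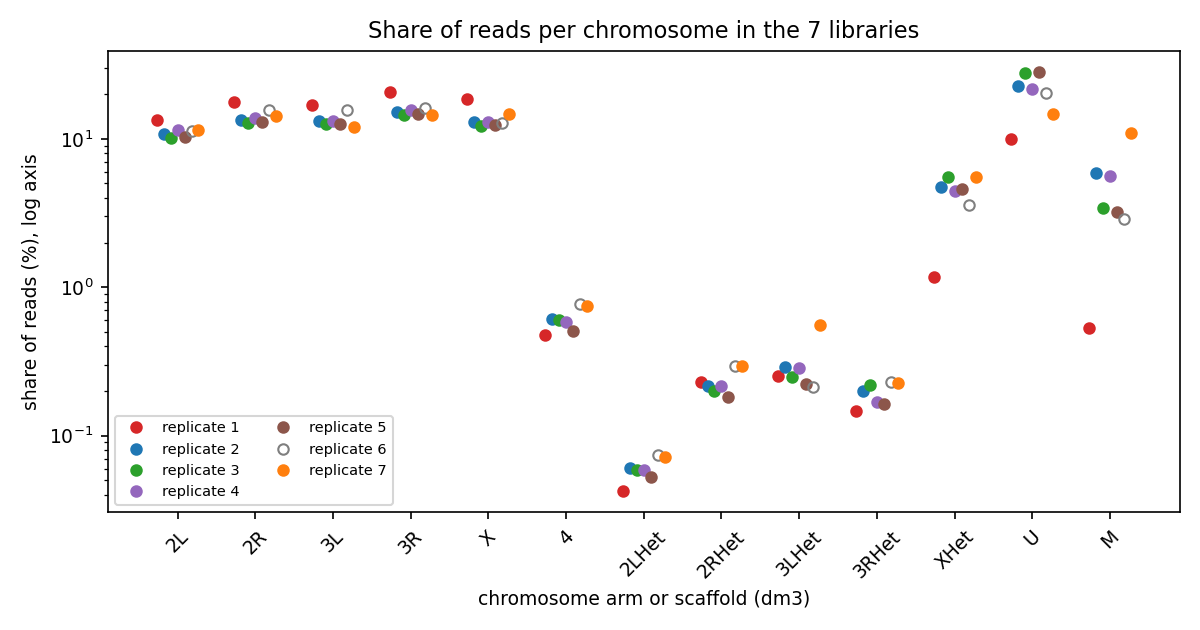
Share of reads (percent, log axis) on each chromosome arm or scaffold of dm3 in each of the 7 libraries; each point is 1 library and the open grey circle is replicate 6. Replicate 1 lies lowest on XHet (1.18%), U (9.94%) and M (0.532%) and highest on the arms; YHet is not drawn.

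Relative to the mean read density of the autosomal arms, the mitochondrial genome, which encodes subunits of the respiratory chain and its own ribosomal RNAs, stood highest. Its log2 ratio was 8.35 ± 1.63 (SD, n = 6), which is 326-fold on average, or 500-fold (log2 8.97) without replicate 1, and it was positive in 6 of 6 libraries. The heterochromatic scaffolds, rich in repeats and here including U, had a pooled log2 ratio of 1.17 ± 0.74, or 2.25-fold, and lay above the arms in 5 of 6 libraries; replicate 1 had −0.22. Taken one by one, after the data were seen, XHet (5.14 ± 1.02) and U (1.79 ± 0.74) lay above the arms in 6 of 6 libraries. The other scaffolds lay below them in 6 of 6, with −1.88 ± 0.40 for 2LHet, −2.29 ± 0.52 for 3LHet, −2.94 ± 0.38 for 3RHet, −3.07 ± 0.25 for 2RHet and −9.50 ± 0.67 for the nearly empty YHet. The X had a ratio of 0.12 ± 0.09 on the log2 scale, positive in 6 of 6 usable libraries, and −0.10 in replicate 6. Chromosome 4, the small and largely heterochromatic chromosome of the fly, had −0.38 ± 0.35 and lay below the arms in 5 of 6 libraries. None of the 4 comparisons passed an adjusted p of 0.05: the two-sided exact sign-flip permutation p was 0.03125, the smallest that 6 libraries allow, for the X and the mitochondrial genome and 0.0625 for the other 2, and the Benjamini-Hochberg adjusted p was 0.0625 for all 4. Without the top 1% of bins of each library, the ratio of the heterochromatic scaffolds became −3.39 ± 0.26, that of the X −0.04, that of chromosome 4 0.023 and that of the mitochondrial genome 1.67. The position of the pooled scaffolds above the arms thus rested on bins within the top 1% and on U and XHet.

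The 20 bins with the highest mean share formed 16 regions and together held 28.9% ± 8.94 of all reads (SD, n = 6). Of these bins, 8 lay on U, 4 on the mitochondrial genome, 4 on X, 3 on XHet and 1 on 2L. The highest region, U 5727001 to 5728000, held 10.5% ± 4.16 of the reads, with its apex at base 5727183. U 9063001 to 9065000 followed with 2.56% ± 0.873, XHet 191001 to 192000 with 2.46% ± 1.23 and M 1001 to 3000 with 2.27% ± 1.66. U 9660001 to 9661000 held 1.71% ± 0.879, U 4571001 to 4572000 held 1.7% ± 0.64, M 12001 to 14000 held 1.63% ± 1.09, U 6962001 to 6963000 held 1.3% ± 0.507 and XHet 184001 to 185000 held 1.14% ± 0.599. The regions on the arms and X were lower than these, but not lower than every region on U and XHet. X 9047001 to 9049000 held 0.751% ± 0.263, X 5726001 to 5727000 held 0.55% ± 0.756 (0.246% ± 0.149 without replicate 7, when it is not among the 20 highest bins), X 18962001 to 18963000 held 0.439% ± 0.193 and 2L 21680001 to 21681000 held 0.341% ± 0.267. The other 3 regions of this list, XHet 194001 to 195000, U 3545001 to 3546000 and U 9578001 to 9579000, held 0.703% ± 0.391, 0.498% ± 0.289 and 0.334% ± 0.171. The lower places of the list depended on single libraries for other regions too. The 2L region left the 20 highest bins without replicate 2 or without replicate 4, and U 9578001 to 9579000 without replicate 3 or without replicate 5. X 9047001 to 9049000 kept 1 of its 2 bins there without replicate 1 or without replicate 7.

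The share of these regions differed between libraries by more than counting error. U 5727001 to 5728000 held 5.5% of reads in replicate 1 (95% interval 54890.01 to 55103.55 RPM), 5.8% in replicate 7 and between 10.8% and 15.1% in replicates 2 to 5. X 5726001 to 5727000 ranged from 0.0194% in replicate 1 to 2.07% in replicate 7. Replicate 1 was the lowest usable library in 16 of the 20 bins. Its summed share was 11.1%, against 30.3% to 35.2% in the other usable libraries and 25.6% in replicate 6. The bins were chosen by the mean share over the usable libraries themselves. A library unlike the rest tends to be low in bins chosen this way, so these values are a description only.

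**Figure D2:**
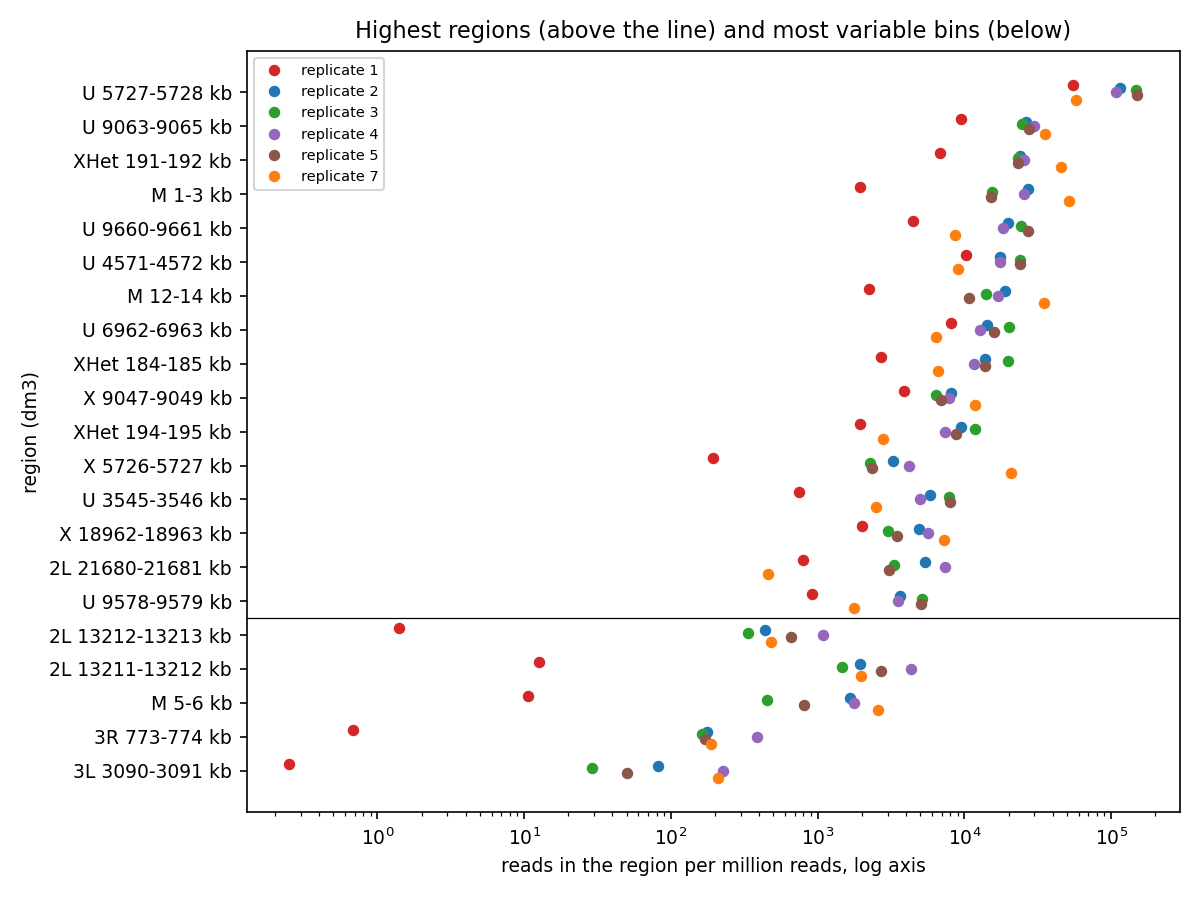
RPM (log axis) in the highest regions, above the line, and in the 5 most variable bins, below it; each point is 1 of the 6 usable libraries and coordinates are dm3. Replicate 1 lies furthest left in most regions, and replicate 7 lies furthest right in X 5726001 to 5727000 (2.07% of its reads).

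Among arms, the highest bin of 3R, at 5609001 to 5610000, held 0.302% ± 0.0912 of reads, that of 2R, at 7871001 to 7872000, 0.185% ± 0.1, and that of 3L, at 828001 to 829000, 0.174% ± 0.0618 (SD, n = 6). The highest bins of chromosome 4, at 87001 to 88000, and of 3RHet, at 790001 to 791000, varied little between libraries, with SDs of log2 share of 0.19 and 0.18. The 5 bins with the largest SD were 2L 13212001 to 13213000 (SD 3.26 on the log2 scale), the neighbouring 2L 13211001 to 13212000 (3.07), M 5001 to 6000 (2.89), 3R 773001 to 774000 (2.87) and 3L 3090001 to 3091000 (2.77). Without replicate 1 these SDs were 0.65, 0.60, 1.01, 0.52 and 1.28. Replicate 1 was the lowest in all 5, with log2 shares that differed by −7.85 to −6.18 from the mean of the other usable libraries. In 2L 13211001 to 13212000 it had 12.6 RPM, against a mean of 2073.06 over the 6 libraries. That bin and its neighbour on 2L hold a single peak across their border, 78 bases wide (13211941 to 13212018) at 5% of its height. The 2 bins are therefore not independent features.

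Reads on the mitochondrial genome were uneven along its length. Positions 1001 to 2000 held 22.2% ± 3.22 of the mitochondrial reads, 2001 to 3000 held 22.3% ± 2.85, 12001 to 13000 held 25.4% ± 5.84 and 13001 to 14000 held 9.75% ± 1.86 (SD, n = 6). Positions 14001 to 15000 held 5.16% ± 2.62, and 11001 to 12000 held 4.53% ± 0.573. The end of the sequence, 15001 to 19515, held 0.0033% ± 0.0055. The profile kept its main maxima in libraries whose mitochondrial share differed from 0.532% to 10.96%: the bin 12001 to 13000 held 35.9% of mitochondrial reads in replicate 1 and between 20.7% and 28.7% in the others.

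**Figure D3:**
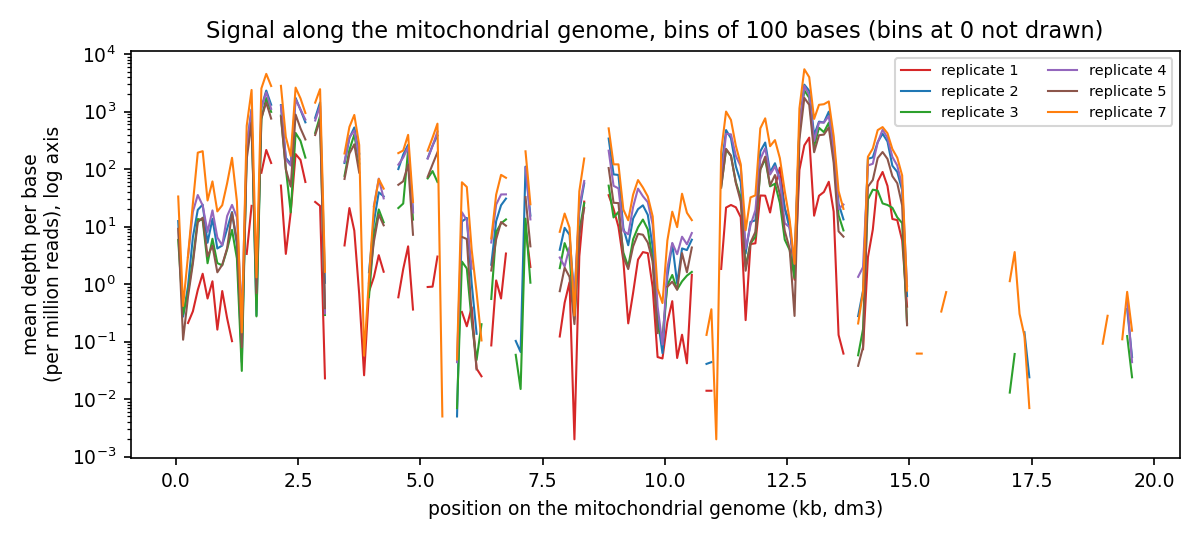
Mean depth per base (scaled to RPM, log axis) along the mitochondrial genome in bins of 100 bases, 1 line per usable library. The highest values lie between 1001 and 3000 and between 12001 and 14000, and few reads lie beyond 15001.

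The signal was concentrated in few bins. The top 1% of bins, 1397 of 139666, held 61.1% ± 6.65 of the reads (SD, n = 6), from 47.8% in replicate 1 to 66.7% in replicate 7. Within the arms and X alone, the top 1% of bins held 43.1% ± 4.05. Any signal was present in 37.9% ± 9.44 of bins. A total of 27710 bins had signal in all usable libraries and 83009 in at least 1, and 40.6% of bins had none in any. A bin without reads in replicate 4 was below what 3 reads give there, 3.321 RPM, so absence cannot be read from that library at low levels.

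The second question was how well the libraries of this background match. Across 83009 bins, Pearson's r averaged 0.931 ± 0.0394 (SD over 15 pairs) and Spearman's rho 0.838 ± 0.0395. Replicates 2 and 3 were the closest pair (r = 0.988) and replicates 1 and 7 the most distant (r = 0.857). Libraries drawn with counting error alone gave a mean r of 0.983 over the same bins, from 0.964 to 0.994. Replicate 6 had r between 0.467 and 0.518 with the usable libraries, and counting error alone at its depth gave 0.513 to 0.523. Among 13646 bins with a mean of at least 10 RPM, the median SD of log2 share was 0.59, against 0.13 with counting error alone. It was 0.45 without replicate 1 and 0.28 without replicates 1 and 7, which was computed after the data were seen. With only bins of at least 1 RPM, r averaged 0.841.

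**Figure D4:**
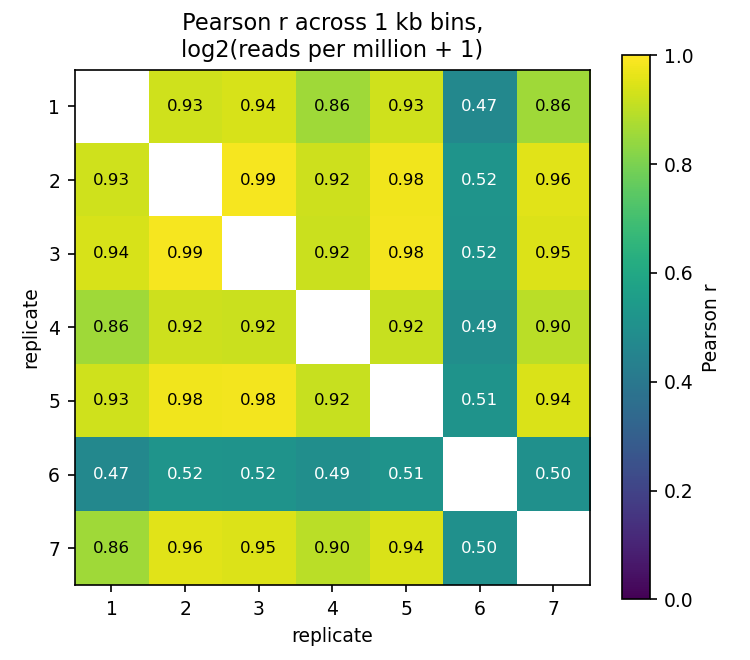
Pearson's r across 1 kb bins on log2(RPM + 1) for each pair of the 7 libraries. Pairs of replicates 2, 3 and 5 reach 0.98 to 0.988, and pairs with replicate 6 lie between 0.467 and 0.518.

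Shares were also set against depth, as log10 of covered bases, across the 7 libraries. The mitochondrial share had r = 0.183 (exact permutation p = 0.607) and rho = 0.0714 (exact permutation p = 0.906). The share on heterochromatic scaffolds had r = −0.0408 (exact permutation p = 0.929) and rho = −0.321 (exact permutation p = 0.498). The share in the top 1% of bins had r = −0.474 (exact permutation p = 0.179) and rho = −0.571 (exact permutation p = 0.2). Over these 6 relations the Benjamini-Hochberg adjusted p was 0.6 or higher. Without replicates 4 and 6, the farthest from the median depth, r was −0.177, −0.866 and −0.722. No relation with depth was shown, and the labels give no batches within which to repeat it.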

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

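Of the tests in this part, those of depth, of a few regions taking much of the signal and of bins 8-fold apart were chosen after the result was seen; the test of short RNAs was written before. The test of a few regions was set after 3 earlier forms had been seen: 2 on the 8-fold bins were void, as the choice of those bins fixed their outcome, and 1 by the spread over bins left the explanation open. The test of depth was first made on the summed share of M, U and XHet alone. Of 50 values examined for a library far from the others, 18 had one, where chance gives about 1 in 20, or 2.5; the values are not independent of each other. The 5 bins named for their large spread were chosen for what this looks for, so chance does not apply to them. Of these, 4 are among the 18, the neighbouring 2L bins with a shared peak included, and without them it was 14 of 45 values. The same rate, that of Dixon's test at 5%, would give 2.25, but it holds for unselected values. Many of the 45 are bins picked for a high mean share in these same libraries, so the 2.25 is a rough guide only. Replicate 1 was the library far from the others in 17 of the 18 and replicate 7 in 1.

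For the chromosome shares, the others are all 6 other libraries. Replicate 1 held more of its reads on the arms, with 13.4% on 2L (others 10.1% to 11.4%), 20.8% on 3R (others 14.4% to 16.1%) and 18.4% on X (others 12.1% to 14.7%). Its top 1% of bins held 47.8% of reads (other usable libraries 62.6% to 66.7%; replicate 6, 68.0%). For the bins that follow, the others are the other usable libraries, without replicate 6. The log2 share of replicate 1, log2(RPM + 1), was low in XHet 191001 (12.73; others from 14.49), U 9063001 (12.65; others from 14.01), U 9064001 (11.58; others from 12.98) and X 9048001 (9.23; others from 11.73). On the mitochondrial genome it was 9.84 in the bin from 1001, 8.40 in the bin from 13001 and 3.54 in the bin from 5001, where the others began at 12.90, 11.70 and 8.82. On the arms it was 1.26 in 2L 13212001, 3.76 in 2L 13211001, 0.75 in 3R 773001, 7.78 in 2R 7871001 and 8.94 in 3L 828001. It was higher than the others only in YHet 328001 among these bins, with 2.11 against at most 1.13, from few reads. Replicate 7 held 0.555% of its reads on 3LHet, where all 6 other libraries held 0.213% to 0.288%.

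Replicate 1 also stood apart across the arms and X: of 13392 bins, 37 were at least 8-fold lower and 134 at least 8-fold higher than in every other deep library, against 3 lower and 0 higher in replicate 7 and 0 in replicates 2, 3 and 5. This rule misses bins of replicate 7 where replicate 1 departs in the same direction. The log2 ratio to the mean of the other deep libraries had an SD over these bins of 1.35 in replicate 1 and 1.07 in replicate 7. It was 0.33 to 0.39 in replicates 2, 3 and 5, so replicate 7 stood apart from them too. A smaller share taken by a few abundant regions changes all other bins by 1 factor, which cannot leave bins apart in both directions. Counted afresh after rescaling to the reads of the arms and X, 85 bins were at least 8-fold lower and 51 at least 8-fold higher (exact Poisson interval of the 51, 38.0 to 67.1), against at most 3 in either direction in another deep library. The interval treats bins as independent, which neighbouring bins are not, and measures no spread between libraries. Bins apart in both directions argue against that explanation as the whole cause. A part may be left to it. Rescaling lowers replicate 1 against the others by construction, so the turn from more higher to more lower bins cannot size that part. A straight-line effect of greater depth is argued against only for some shares. Lines of share against log10 reads were drawn through the other 4 deep libraries. From these, replicate 1 lay 6.48 prediction errors away on 3R, −7.98 on XHet and, barely, −4.32 for the top 1% of bins, where the 95% bound is 4.30. For these shares, replicate 1 was outside the 95% interval of the lines through all 6 other libraries as well. All these lines are extrapolated, as replicate 1 held 17522340 reads and the next deepest library 8003741. An effect of depth that is not a straight line stays open for every share. Depth stays open for U (0.35), X (0.81), 2L (1.05) and M (−2.04), and for all heterochromatic scaffolds (−0.14) and the summed M, U and XHet (−2.56). On the lines through all 6 other libraries (bound 2.78), replicate 1 was inside for U (−2.1) and M (−1.72). It was outside for 2L (4.28), X (4.45), all heterochromatic scaffolds (−2.94) and the summed share (−8.53). Shares were sorted by these outcomes. Without replicates 4 and 6 the heterochromatic share and the top 1% share fell with depth over the 5 deep libraries (r −0.866 and −0.722). These values include replicate 1, the deepest, so they cannot decide whether depth sets it apart. A loss of short RNAs in replicate 1 stays open, as isolated covered stretches of at most 400 bases had a median log2 ratio −0.96 from that of stretches of 1000 bases or more (bootstrap interval −1.23 to −0.77), short of the −1 set beforehand. The design has 1 group, so no biological explanation was tested, and a difference in RNA preparation or culture may remain.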

How the results depend on the processing

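All alternatives for the named regions, and the spread without each library, were chosen after seeing the data; the others were planned. For chromosome ratios, concentration and agreement, 61 alternatives kept the direction and the side of the threshold, or moved by less than 1 SD. Leaving out the top 1% of bins turned 3 signs, X to −0.04, chromosome 4 to 0.023 and the heterochromatic scaffolds to −3.39 (log2); high bins are removed by construction, so the ratios describe the remaining, weakly covered sequence. With all 7 libraries, 3 comparisons passed the threshold at an adjusted exact p of 0.04167: chromosome 4 (−0.34), the scaffolds (1.16) and the mitochondrial genome (8.29); 1 more library allows smaller p-values. Leaving out each library gave 0.09 to 0.14 for X, −0.47 to −0.26 for chromosome 4, 1.05 to 1.45 for the scaffolds and 8.02 to 8.97 for the mitochondrial genome; with 5 libraries the exact test cannot pass 0.05. The top 0.1% of bins held 40.6% of reads by construction, the top 1% of 10 kb bins 48.0%, and 68.6% of 10 kb bins had signal. Mean r was 0.974 and rho 0.929 with 10 kb bins, and r was 0.841 with bins of at least 1 RPM, for which the cause was not tested. With all 7 libraries r was 0.808 and rho 0.702, through the added pairs of replicate 6: these averaged r 0.502 and rho 0.364, against 0.52 and 0.369 from counting error alone at its depth. Of the named regions, 108 alternatives moved the log2 share by less than 1 SD, and X 9047001 moved to 12.39 as a share of the arms and X. The correlations with depth passed no threshold under any alternative; 5 of 6 alternatives kept the sign, and that of the mitochondrial share changed sign to −0.137 with usable libraries. Alternatives for annotated features and gene groups were not run. Depth limits replicates 4 and 6 most.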

Other observations

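In this part, the test of reads split across removed introns was written before its result was seen; the other tests were chosen after. The coverage held many short gaps with sharp edges, where at least 5 reads on both sides dropped to 0. There were 9433 in replicate 1, 7318 in replicate 3, 6557 in replicate 2, 5882 in replicate 5 and 5433 in replicate 7, with median lengths of 64 to 65 bases. A total of 1274 gaps had identical coordinates in all 5 deep libraries, with 326 on 3R, 306 on 2R, 230 on 3L, 211 on 2L, 169 on X and 12 on chromosome 4. A further 8 lay on U and 4 on the mitochondrial genome. The median length of the 1274 gaps was 64 bases, the most frequent length 61, and 83.2% were 50 to 80 bases long. In Drosophila, many introns are short.

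Stacks of duplicate reads are argued against as the cause of these gaps, because at least 65.76% of the gaps of each deep library recurred exactly in another. The same recurrence argues against chance gaps between reads in the 5 deep libraries, as gaps placed by chance would seldom recur exactly. There, lengths of 50 to 80 bases were at least 5.764 times as frequent as among gaps bordered by single reads. Gaps bordered by single reads lie at lower depth, so this comparison of lengths alone cannot exclude chance. The ratio was 3.127 in replicate 4, and replicate 6 had only 3 sharp-edged gaps. Reads split across removed introns had the values this explanation needs. In the sparse libraries 4 and 6, pairs of neighbouring isolated blocks whose lengths summed to exactly 50 bases were at least 80.58 times as many as pairs at neighbouring sums. Of these 367 pairs in replicate 6, 71.4% enclosed a gap equal to a sharp-edged gap of a deep library, and 73.6% of 1112 did in replicate 4, which is consistent with spliced RNA in the background.

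A second pattern concerned height without width. In 7 of the 16 highest regions, all on U or XHet, at least 90% of the reads lay over a single base. There the peak was 50 bases wide at 50% of its height, and 56 to 96 bases wide at 5% of its height. XHet 184001 had 99.9% ± 0.02 of its reads over its apex (SD, n = 6), U 9660001 99.9% ± 0.07 and XHet 191001 93.4% ± 2.09, against 14.5% ± 1.34 in X 18962001 and 5.74% ± 2.52 in X 9047001. Narrow windows were counted as runs of bases with at least 2 RPM, at most 100 bases long, with at least 50 RPM at the peak. Each usable library had 58 to 76 of these windows, which held 9.03% ± 2.53 of its reads. Peaks with flanks of 2 RPM or more beyond 100 bases were not counted, so the 7 regions need not all be among the windows. Amplification of single molecules is argued against for replicates 2, 3, 5 and 7, where at least 81.58% of windows overlapped a window of another deep library. For replicate 1 it stays open, with 56.9% (33 of 58, exact interval 43.2% to 69.8%). Repeats in which few positions can be told apart may contribute and stay open: windows were 2.83 to 6.17 times as dense on the heterochromatic scaffolds as on the arms and X, and the reads in them 82.4 ± 16.2 times as dense per base (SD, n = 6). The aligner's rule for such reads is not given. No biological explanation was tested.

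Replicate 7 departed from replicates 2 to 5 in both directions. Its log2 share was 2.82 above their mean in X 5726001 to 5727000, 1.35 above in M 1001 to 3000 and 0.93 above in XHet 191001 to 192000. The difference was −3.29 in 2L 21680001 to 21681000, −1.73 in XHet 194001 to 195000 and −1.15 in U 5727001 to 5728000. It was below each of replicates 2 to 5 in 9 of the 20 highest bins and the highest usable library in 11.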
